A study of Mus musculus with 4 samples.

How the data were processed

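The series holds 4 RNA-seq libraries from mice of 8 to 12 weeks whose back skin was treated with imiquimod cream (5%) for 5 days. Per the labels' protocols, the daily amount was 15 or 62.5 mg, and which amount each mouse received is not given in the sources used here. Per the labels' protocols, dermal cell suspensions were made from dorsal skin with dispase and collagenase and stained for CD45 and CD4, and cDNA was made with oligo-dT priming and SMART amplification before library construction with a transposase and circularisation. The labels name the cells CD4+ T cells. The gate that was used to collect them is not given in the sources used here. No molecular identifiers are described, so confidence intervals and the limits set by a count of 0 cover counting error only.

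The values in the deposited tables are raw fragment counts per annotated exon. Per the file headers, featureCounts 2.0.1 counted pairs with both ends mapped and not chimeric, without strand, on alignments to GRCm38, against GENCODE M23. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.7 and aligned with STAR 2.7.9a. Sambamba appears in the name of the alignments per the file headers, with no setting stated, so whether duplicates were removed is not given in the sources used here.

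Per the file headers, counting was by exon entry rather than by gene, and a fragment that overlapped more than 1 entry was not counted. Each table has 841606 exon entries of 55335 genes, and 545076 of them (64.8%) share their coordinates with another transcript's entry of the annotation. All of those entries held 0 fragments in the 4 libraries. The deposited counts of a gene therefore come only from exons annotated in a single transcript, and 8.30% of all fragments lay in exons that GENCODE M21 gives to retained-intron transcripts alone. Of the exon entries, 99.7% had the same gene and coordinates in GENCODE M21, which was used for transcript types. The exons that could be counted were the same in every library. A gene's counts can be compared between libraries only if fragment lengths were alike, since longer fragments more often overlap more than 1 entry. Fragment lengths were not examined. A difference in a gene's counts can also come from transcript use or retained introns rather than the level of the gene. Levels of different genes can be compared only roughly. Fragments that mapped to several places were not counted, so members of near-identical families such as Sprr2, Ly6c, Ifi200 and Ifit genes are uncertain. Where exons of genes on opposite strands overlap, fragments were not counted for either gene. Elsewhere, RNA from the strand opposite an exon cannot be told apart from that of the exon.

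From these counts, the exon entries of each gene were summed, and symbols were matched for 55154 gene identifiers, leaving 181 without one. Totals were 4537006 fragments in control 1, 3614418 in control 2, 4316904 in knockout 1 and 4353365 in knockout 2. At these depths a count of 0 allows a level of up to 0.655 to 0.792 CPM (3 fragments per library, as TMM-scaled CPM, the unit of all levels given). The libraries were numbered within each genotype only to name them, since the labels number no replicates, and no label states a pairing or a batch. Whether the sample titles hold dates or animal numbers is not given in the sources used here. Nothing says how many mice contributed to a library, so p-values measure the spread between these libraries. No pair of libraries agreed within sampling noise (chi-square per degree of freedom from 46.1 to 197.3), which cannot show that they came from different mice. All 4 were used as separate replicates.

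The comparison of knockout with control libraries used edgeR 4.0.16 (R 4.3.3) with filterByExpr at a minimum count of 10, TMM factors, the quasi-likelihood test, no covariates and Benjamini-Hochberg adjustment over 12434 genes at 0.05. All tests were two-sided. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over 31 lists with at least 3 tested members, out of 34 lists written before the data were examined. Of the others, 2 had too few tested members and 1, of sex-linked genes, was a check. Camera with an estimated correlation and fry were alternatives. The design, the lists, the first set of alternatives and the rule for naming genes were fixed before the data were examined. Genes named are Mettl3, the 5 genes with the lowest p in each direction at a mean of at least 5 CPM (used because fewer than 5 genes passed the threshold in either direction), 18 T cell and SOCS genes, the 4 members with the lowest p of each list past the threshold, and the member with the highest mean CPM of each list for another cell type. Predicted genes, RIKEN clones, pseudogenes and small RNAs were left out of the second group. A few genes that the rule takes are not reported here. Confidence intervals of shares are exact binomial intervals at 95%.

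Alternatives were median-ratio and upper-quartile factors, library totals alone, no low-count filter, a mean of at least 5 CPM, no mitochondrially encoded and ribosomal protein genes, limma-voom, DESeq2 1.42.0, thresholds of 0.1 or of a log2 fold change over 1, and each library left out in turn. A covariate for the presence of Y-linked transcripts, a minimum of 1 fragment in every library, and sums without retained-intron exons were chosen after seeing the data. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, intervals and plots.

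The test was tested on simulated data with the real libraries' means and totals and 200 changed genes among 12434. The spread was first taken from these libraries as a trend over abundance (their common biological coefficient of variation was 1.17). With that spread, the test recovered 0% of genes changed 2-fold, 0% of those changed 4-fold and 14% of those changed 16-fold. With a spread of 0.2 it recovered 18.5%, 87% and 92.5%. A single value compared between 2 and 2 libraries cannot go below an exact permutation p of 0.3333.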

Results

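Imiquimod, an agonist of Toll-like receptor 7, gives mouse skin a psoriasis-like inflammation in which interleukin-17-producing lymphocytes take part. The RNA of cells labelled as CD4+ T cells from such skin was sequenced in 2 mouse genotypes, with 2 libraries each. The control libraries came from mice with floxed Mettl3 alleles, and the knockout libraries from mice that also carried Cre recombinase under the Cd4 promoter, which is active in developing T cells. Mettl3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA. The comparison asks which transcripts differ in skin CD4+ T cells when Mettl3 is deleted in T cells. Counted fragments per library were between 3614418 and 4537006. Control 1 had fragments of 19378 genes, control 2 of 11424, knockout 1 of 20100 and knockout 2 of 16273.

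Mettl3 (ENSMUSG00000022160, GRCm38 chromosome 14, 52294841 to 52305128, minus strand) did not differ detectably between the genotypes. Control 1 had 195 fragments, control 2 had 49, knockout 1 had 121 and knockout 2 had 158, or 27.8 ± 20.9 CPM in controls and 33.8 ± 5.06 CPM in knockouts (SD, n = 2 each). The log2 fold change was 0.28 with a standard error of 1.16 (edgeR quasi-likelihood test, adjusted p = 0.9997), and it was -0.34 without control 2, 1.45 without control 1 and 1.59 without retained-intron exons. Of the gene's 71 exon entries, 6 held fragments, and 4 of these belong to retained-intron transcripts, which held 89.9% of the fragments. The entry with most fragments (52303621 to 52305124) had 165, 26, 85 and 120 in control 1, control 2, knockout 1 and knockout 2. The 2 other entries belong to transcripts annotated for nonsense-mediated decay, so no fragment was counted in an exon given to a protein-coding transcript, and the deleted part of the gene is not given in the sources used here. These counts check nothing about the deletion.

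**Figure D1:**
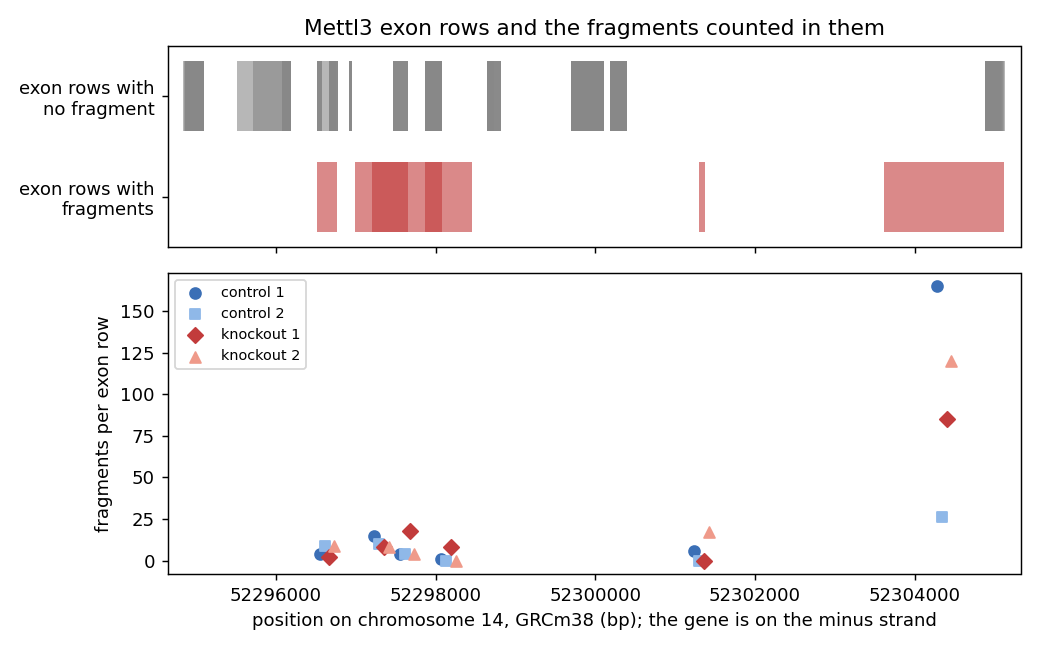
Mettl3 exon entries along GRCm38 chromosome 14 (upper panel, position in base pairs), split by whether they held any fragment, and the fragments counted in each of the 6 entries that did (lower panel, 1 point per library, offset sideways for legibility). Most fragments fell in the entry from 52303621 to 52305124, where control 1 had 165 and knockout 2 had 120.

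Macrophage, fibroblast and keratinocyte markers held more counted fragments than T cell genes in every library, though the lists differ in length and in how many of their exons could be counted. The list of T cell identity and receptor signalling genes held 0.139% of fragments in control 1 (exact 95% interval 0.135 to 0.142), 0.0443% in control 2 (0.0422 to 0.0466), 0.0655% in knockout 1 (0.0631 to 0.0680) and 0.0358% in knockout 2 (0.0340 to 0.0376). Macrophage and monocyte markers held 2.27%, 1.15%, 3.24% and 3.13% in the same order. Their most abundant member was Lyz2, the lysozyme of myeloid cells, at 9378 CPM in control 1, 3876 in control 2, 14350 in knockout 1 and 10810 in knockout 2. Cd4 itself had 777 fragments in control 1, 0 in control 2, 420 in knockout 1 and 9 in knockout 2, and Cd3e, a chain of the T cell receptor complex, had 282, 1, 80 and 42. Keratinocyte markers held 0.265% in control 1, 3.44% in control 2, 0.312% in knockout 1 and 0.154% in knockout 2, led by Perp, a desmosome-associated protein, at 6580 CPM in control 2 against 100.5 to 442.5 in the others. Fibroblast markers held 1.32%, 0.326%, 0.556% and 0.595%, led by Mmp2, a matrix metalloproteinase (1488 ± 1558 CPM in controls and 1474 ± 671 in knockouts, SD, n = 2 each).

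Control 2 stood apart from the other 3 libraries. Across genes, its log2 CPM correlated with theirs at a Pearson r of 0.621 to 0.626, against 0.827 to 0.865 among the others, where genes are not independent replicates. Among the 12434 genes tested, 4064 had no fragment in control 2, against 229 in control 1, 221 in knockout 1 and 860 in knockout 2. Mitochondrially encoded transcripts made up 7.98% of its fragments, against 2.76% in control 1, 2.29% in knockout 1 and 4.39% in knockout 2. The median absolute log2 difference between the 2 controls was 1.86, above the 0.789 between the 2 knockouts and the 0.633 and 0.665 between control 1 and each knockout.

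**Figure D2:**
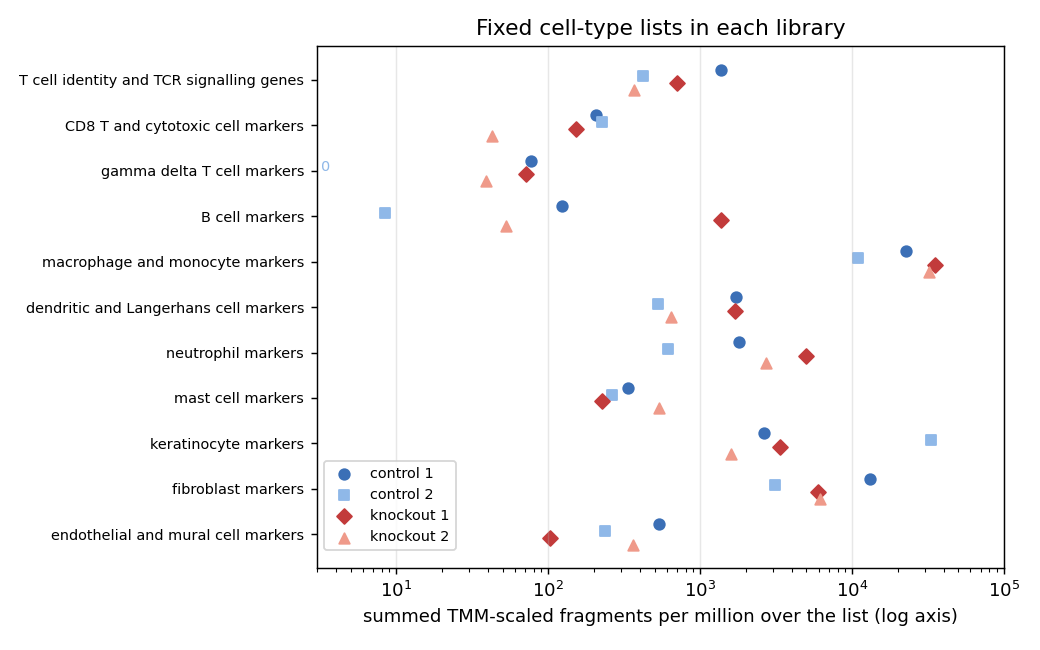
Summed level of each fixed cell-type list but the erythroid one in each library, as TMM-scaled CPM on a log axis, with 1 point per library and a printed 0 where no fragment was counted. Keratinocyte markers sum to 32774 in control 2 and to 1582 to 3368 in the other libraries, and T cell identity genes sum to 1374 in control 1 and to 368 to 706 in the others.

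No gene passed the threshold between knockout and control libraries, and the genes with the lowest p on the higher side included Il1a, Cd38, Ccr1 and Map3k4. Il1a, the cytokine interleukin-1 alpha (chromosome 2, 129299610 to 129309972), was at 133.9 ± 17.7 CPM in controls and 708.7 ± 45.4 in knockouts (SD, n = 2 each), a log2 fold change of 2.40 with a standard error of 0.53. Cd38, an ectoenzyme that breaks down NAD (chromosome 5, 43868553 to 43912375), was at 128.7 ± 45.0 and 799.0 ± 182.8 CPM (log2 fold change 2.63), and Ccr1, a chemokine receptor (chromosome 9, 123962124 to 123968692), at 524.0 ± 24.3 and 2528 ± 890 CPM (2.27). Map3k4, a stress-pathway kinase (chromosome 17, 12227621 to 12318796), had 0 fragments in both controls and 73 and 135 in the knockouts, at least 34.6-fold higher against a floor of 3 fragments per library, with 98.1% of its fragments in a retained-intron exon.

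On the lower side, the 5 genes with the lowest p were Lrat, Lce3d, Bbox1, Sprr2k and Sprr1a, none past the threshold. Sprr1a, a precursor of the cornified envelope (chromosome 3, 92483952 to 92485895), was at 167.9 CPM in control 1, 818.8 in control 2 and 46.5 ± 3.84 in knockouts (SD, n = 2), with a log2 fold change of -3.41 (standard error 0.94), or -1.86 without control 2. Lce3d, another such precursor (chromosome 3, 92957390 to 92958505), Bbox1, an enzyme of carnitine synthesis (chromosome 2, 110262697 to 110314560), and Sprr2k (chromosome 3, 92432582 to 92433925) had 0 fragments in both knockouts and were at least 42.0-fold, 97.1-fold and 116.3-fold lower there, against the same floor. Lrat, which esterifies retinol (chromosome 3, 82892579 to 82903973), had 36 and 882 fragments in the controls and 1 and 0 in the knockouts, a pooled ratio of 903.4 with a counting interval of 161.7 to 35720. In control 2, the library with high keratinocyte markers, Bbox1 had 503 fragments and Sprr2k 615, against 40 and 33 in control 1.

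Over all 12434 genes, 187 had an unadjusted p under 0.05 and the lowest adjusted p was 0.9997 (edgeR). DESeq2 called 17 genes, 4 higher and 13 lower, edgeR without a low-count filter called 27, 8 higher and 19 lower, and limma-voom called 0. The calls of DESeq2 included Map3k4 among the higher and Sprr2k, Bbox1, Lrat and Lce3d among the lower genes, at adjusted p from 0.013 to 0.048, and 2 further higher genes, named after their values were seen, were Serpina3k and AC125381.2. Leaving out knockout 1 gave 2 calls, Xist and Serpinb3d, leaving out knockout 2 gave 4, all immunoglobulin genes (Igkc, Igkv8-34, Igkv14-111 and Ighv5-17), and leaving out either control gave 0. Of these only Igkc was named by rule. Xist had 1858 and 8909 fragments in the controls and 20 in knockout 2, the only knockout left in that setting. Knockout 2, like control 1, held Y-linked transcripts. The setting without control 1 had many genes only slightly above the threshold. Both knockouts lay above both controls for 2425 genes (19.5%) and below for 1396 (11.2%), where chance gives 16.7% in each direction. The median log2 fold change of all genes was 0.20, between 0.09 and 0.26 under the other scalings, so a difference of this size is the common shift.

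Among 31 gene lists, 3 were higher and 6 lower in the knockouts by camera with a preset correlation. With an estimated correlation the adjusted p of all 9 was 0.940, and fry, which asks whether a list's own genes move one way on balance, gave 0.906, so no call held under either. These were the lowest adjusted p of any of the 31 lists in each test, so they do not tell the lists apart. Both tests rest on few libraries. Even keratinocyte markers had an unadjusted p of 0.163 by camera with an estimated correlation. No member of any of the 31 lists passed the threshold over all genes or adjusted over the list alone.

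Type I interferon response genes, which encode antiviral proteins, were higher in the knockouts as a list. Of 27 tested members, 24 had a positive log2 fold change, with a median of 2.06 (adjusted p = 7.1e-07; 0.940 as adjusted p with an estimated correlation), and 15 had both knockouts above both controls. Ifi209, an interferon-inducible DNA sensor, had 24 fragments in each control and 503 and 193 in the knockouts (log2 fold change 3.88, standard error 1.13). Ifit3b, an interferon-induced antiviral protein, had 1 and 0 fragments in the controls and 102 and 63 in the knockouts. Its pooled ratio was 167.7 (counting interval 29.7 to 6662). Ifi213 had a ratio of 70.1 (19.1 to 584.7), with 28.95 CPM in knockout 1 and 5.20 in knockout 2. The nucleotide kinase Cmpk2 had one of 53.4 (14.4 to 446.3), with 22.2 CPM in knockout 1 and 3.78 in knockout 2. The list's summed level was 777.8 CPM in control 1, 295.9 in control 2, 2295 in knockout 1 and 1094 in knockout 2. The call remained in all 15 alternatives with a preset correlation, at adjusted p from 1.6e-09 to 0.0041. The median was 0.68 over genes with a fragment in every library, 8.12 without control 1, where many members are compared with 0 fragments, and 1.46 without control 2.

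Markers of myeloid cells were higher in the knockouts beside the interferon list. All 20 tested macrophage and monocyte markers had a positive log2 fold change, with a median of 1.05 (adjusted p = 0.00013; 0.940 as adjusted p with an estimated correlation), and 14 had both knockouts above both controls. Cd14, a co-receptor for lipopolysaccharide, was at 1991 ± 1434 CPM in controls and 6748 ± 53.5 in knockouts (SD, n = 2 each). Fcgr1, an antibody receptor, was at 147.8 ± 142.9 and 625.8 ± 123.8 CPM. Ly6c2, a marker of inflammatory monocytes, was at 9.64 ± 7.66 and 125.1 ± 8.06 CPM, with 99.9% of its fragments in a retained-intron exon. The list was called in all 15 alternatives with a preset correlation, at adjusted p from 2.2e-07 to 0.0073, with a median of 2.69 without control 1 and 0.56 without control 2.

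Neutrophil markers had a median log2 fold change of 1.61, with 6 of 7 members positive (adjusted p = 0.021; 0.940 as adjusted p with an estimated correlation). Clec4d, a lectin receptor, was at 27.1 ± 12.6 CPM in controls and 188.4 ± 13.4 in knockouts, Mmp8, neutrophil collagenase, at 287.1 ± 78.6 and 1085 ± 625, G0s2, an inhibitor of lipolysis, at 63.7 ± 17.7 and 194.4 ± 136.9, and S100a8, a calcium-binding alarmin, at 15.4 ± 5.45 and 58.5 ± 22.0 (SD, n = 2 each). Mxd1, the member with the highest level, was at 766.9 ± 728.8 and 2248 ± 1121 CPM. S100a8 had 75.8% of its fragments in a retained-intron exon and a log2 fold change of 1.92, or -0.13 without such exons. The list's call was lost without control 1 (median 2.56), with the Y-linked covariate (median 1.81, adjusted p = 0.083) and without retained-intron exons (adjusted p = 0.057). The adjusted p lay within a range of 0.00045 to 0.940 over all alternatives. With 1 library left out, the list's median lay between 1.79 and 2.56.

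T cell identity and receptor signalling genes were lower in the knockouts as a list, with 15 of 20 members negative and a median log2 fold change of -1.06 (adjusted p = 0.024; 0.940 as adjusted p with an estimated correlation). The T cell receptor constant region Trac was at 135.4 ± 88.1 CPM in controls and 30.2 ± 6.66 in knockouts, and Trbc2 at 129.4 ± 85.9 and 27.6 ± 12.6 (SD, n = 2 each). Cd3d, a further chain of the receptor complex, was at 91.6 ± 18.0 and 24.5 ± 0.942 CPM, and the surface protein Thy1 at 118.8 ± 69.8 and 32.2 ± 13.7. Cd4 had a log2 fold change of -0.67 with a standard error of 2.71, and Cd3e one of -1.05 with a standard error of 2.12, and both were positive by limma-voom, with the Y-linked covariate and without control 1 (10.77 and 5.73, against a control 2 with 0 and 1 fragments), and Cd4 also without knockout 2 (0.32). The list's median was 2.10 without control 1 (adjusted p = 0.979), -0.57 without knockout 2 (0.574) and -1.92 without control 2 (4.4e-07). The call was also lost without a low-count filter (0.072), at a mean of at least 5 CPM for genes (0.090) or members (0.062), and with the Y-linked covariate (0.105).

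Type 3 genes, a list written for interleukin-17-producing cells whose members are not all limited to them, were lower in the knockouts by the list test. The members went both ways. Of 15 tested, 8 were negative and 7 positive, with a median log2 fold change of -0.05 and a mean of -0.89 (adjusted p = 0.0097; 0.940 as adjusted p with an estimated correlation). Il17a had 469 fragments in control 1, 56 in control 2, 65 in knockout 1 and 1 in knockout 2, or 58.6 ± 61.9 CPM in controls and 8.23 ± 11.3 in knockouts (SD, n = 2 each; log2 fold change -2.83, standard error 2.06, adjusted p = 0.9997 by edgeR). With 1 library left out, the log2 fold change of Il17a lay between -7.79 and -0.77, the latter without control 1. Il17f was at 105.2 ± 139.8 and 28.5 ± 34.2 CPM, and without control 1 its log2 fold change turned from -1.89 to 2.23. Il22, which acts on keratinocytes, was at 103.7 ± 59.3 and 13.1 ± 18.5 CPM, Il23r, the receptor that sustains such cells, at 37.0 ± 11.2 and 4.37 ± 6.18, and the nuclear receptor Rora at 316.4 ± 40.5 and 88.4 ± 43.5 (log2 fold change -1.84, standard error 0.67). For Il22, Il23r and Rora both knockouts lay below both controls, and their log2 fold changes lay between -11.77 and -1.93, -10.25 and -1.99, and -2.38 and -1.36 with 1 library left out. Rora had 1307 fragments in control 2, where Cd4 had 0, and which cells supplied it was not tested. The list's median was positive while the call stayed with upper-quartile factors (0.012), without a low-count filter (0.051) and without retained-intron exons (0.032). It was 0.29 without control 1 and -0.26 without knockout 2, where the call was lost, and -4.63 without knockout 1 and -0.94 without control 2. The call was also lost at a mean of at least 5 CPM for genes (median 0.014, adjusted p = 0.090) or members (-0.01, 0.062) and over genes with a fragment in every library (0.039, 0.708).

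Other T helper lists did not pass the threshold with all genes and libraries. Type 1 genes had a median log2 fold change of 0.86 over 11 members (adjusted p = 0.290), and passed over genes with a fragment in every library (1.08 over 9 members, 0.0064). Their median lay between 0.61 and 2.17 with 1 library left out. Ifng, interferon gamma, was at 25.5 ± 26.7 CPM in controls and 14.8 ± 21 in knockouts, a direction that turned without control 2 or knockout 2, and Tbx21, its transcription factor, at 2.86 ± 3.67 and 11.6 ± 7.28 (SD, n = 2 each). Type 2 genes had a median of -0.61, with all 6 negative (adjusted p = 0.437). Gata3, their transcription factor, was at 95.2 CPM in control 1, 226.2 in control 2, 85.4 in knockout 1 and 10.2 in knockout 2. Its highest level was thus in the library with high keratinocyte markers. Too few fragments were counted to test Il4 (12, 6, 3 and 0 in control 1, control 2, knockout 1 and knockout 2) and Il13 (0, 0, 0 and 3). Regulatory T cell genes had a median of -0.72 over 14 members (adjusted p = 0.056). Foxp3 had no fragment in any library, which allows up to 0.655 to 0.792 CPM in the exons that could be counted. Ctla4, an inhibitory receptor, was at 39.4 ± 32.6 and 10.8 ± 4.88 CPM, and Il10, an anti-inflammatory cytokine, at 322.8 ± 79.8 and 595.4 ± 342.2. Inhibitory receptor genes had a median of -1.39 over 9 members (adjusted p = 0.054), follicular helper genes -0.47 over 5 (0.854), naive and central memory genes -0.04 over 11 (0.972), tissue residency genes 0.31 over 10 (0.680) and immediate early and activation genes 0.55 over 20 (0.437). Without control 2, the type 2, regulatory and inhibitory receptor lists were lower past the threshold (adjusted p = 0.049, 3.0e-05 and 0.0015), as they were without knockout 1 (0.024, 0.0056 and 0.021). Without control 1 they did not pass, with medians of 6.99, 0.80 and -0.77 (adjusted p = 0.906, 0.831 and 0.547), nor without knockout 2, with medians of -0.60, -0.28 and -1.09 (0.965, 0.425 and 0.363). Regulatory genes were also lower past the threshold by limma-voom (0.035), and inhibitory receptors without a low-count filter (0.041), without retained-intron exons (0.041) and over genes with a fragment in every library (0.0070), where immediate early genes were higher (0.039). The immediate early median lay between 0.20 and 1.16 with 1 library left out.

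No list of signalling genes downstream of cytokines passed the threshold. The SOCS family, which restrains cytokine receptor signalling, had a median log2 fold change of 0.91 over 6 members (adjusted p = 0.727), between -0.20 and 1.68 with 1 library left out. Socs3 was at 1332 ± 1494 CPM in controls and 3858 ± 529 in knockouts (SD, n = 2 each), both knockouts above both controls, Cish was at 9.61 ± 13.6 and 16.8 ± 16.8, and Socs1 had 12, 0, 5 and 9 fragments in control 1, control 2, knockout 1 and knockout 2 and was not tested. JAK-STAT and common gamma chain genes had a median of -0.04 over 16 members (adjusted p = 0.727). Genes of the m6A writer complex had a median of 0.29, with all 5 positive (adjusted p = 0.437), but 2 of 5 positive and a median of -0.19 without control 2 and 3.52 without control 1, and m6A readers and erasers one of 0.33 over 11 (0.733).

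Keratinocyte markers were lower in the knockouts as a list, and this rested on control 2. Of 16 tested members, 15 were negative, with a median log2 fold change of -3.00 (adjusted p = 5.8e-12; 0.940 as adjusted p with an estimated correlation), and without control 2 the median was 0.05 (0.555). Krt1, a keratin of differentiating epidermis, was at 94.7 CPM in control 1, 2290 in control 2, 64.2 in knockout 1 and 54.6 in knockout 2. Krt10, its partner keratin, was at 638.5 CPM in control 2 and 15.7 to 27.5 elsewhere, Sprr1b at 1422 and 37.1 to 174.0, and Lgals7, an epithelial galectin, at 1046 and 24.1 to 53.9. Mitochondrially encoded genes were lower too, with all 17 negative and a median of -0.88 (adjusted p = 0.0028; 0.940 as adjusted p with an estimated correlation). Among them mt-Nd2 was at 2700 ± 2199 CPM in controls and 1287 ± 754 in knockouts, mt-Nd6 at 1056 ± 858 and 524.6 ± 372.4, mt-Atp6 at 57.1 ± 71.5 and 13.6 ± 0.165, and the transfer RNA gene mt-Tn at 15.2 ± 18.8 and 2.42 ± 0.25 (SD, n = 2 each). Cytosolic ribosomal protein genes had a median of -0.30, with 52 of 75 negative (adjusted p = 0.0031; 0.940 as adjusted p with an estimated correlation). Rps23 was at 33.97 ± 25.5 and 5.90 ± 2.69 CPM, Rpl39 at 179.9 ± 161.8 and 77.6 ± 22.6, Rplp1 at 1069 ± 645 and 600.1 ± 184.7, and Rpl22 at 0.437 ± 0.617 and 3.85 ± 1.91. Without control 2 the medians of these lists turned to 0.38 (adjusted p = 0.069) and 0.17 (0.351), and without knockout 1 the calls were lost as well (0.075 and 0.705), the ribosomal one also over genes with a fragment in every library (0.108).

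Proliferation genes were lower in the knockouts as a list, with 16 of 24 negative and a median log2 fold change of -0.62 (adjusted p = 0.024; 0.940 as adjusted p with an estimated correlation). Cenpf, a kinetochore protein, was at 79.0 ± 76.0 CPM in controls and 3.70 ± 3.23 in knockouts, Ccnb2, a mitotic cyclin, at 203.2 ± 128.1 and 52.9 ± 9.93, and Rrm2, which makes deoxyribonucleotides, at 110.5 ± 48.6 and 30.6 ± 25.9 (SD, n = 2 each). Kif11, a spindle motor, went the other way, at 0.655 ± 0.926 and 9.13 ± 1.55 CPM. The call was lost without control 1 (median -0.21, adjusted p = 0.399), without knockout 2 (-0.25, 0.314), without a low-count filter (0.125) and with the Y-linked covariate (0.070), within a range of 0.0041 to 0.940 over all alternatives.

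**Figure D3:**
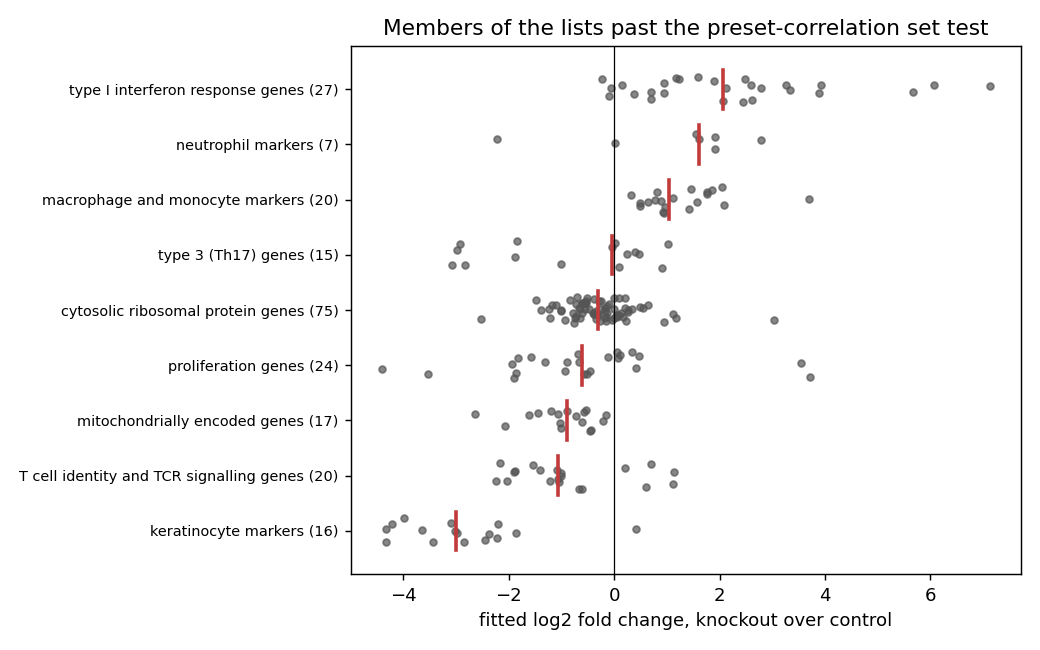
Fitted log2 fold change, knockout over control, of each tested member of the 9 lists past the preset-correlation test (points, jittered vertically), with each list's median as a bar and the number of tested members in brackets. Interferon genes have a median of 2.06 and keratinocyte markers one of -3.00, and no single gene passed the threshold.

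The remaining lists did not pass the threshold. Fibroblast markers had a median log2 fold change of -0.57 over 11 members (adjusted p = 0.113), and were lower past the threshold without control 2 (-1.08, 0.00036) and without retained-intron exons (-0.57, 0.041). Endothelial and mural markers had a median of 0.25 over 8 (0.668), with Plvap, an endothelial membrane protein, at 216.6 ± 238.8 CPM in controls and 71.5 ± 57.7 in knockouts (SD, n = 2 each). Dendritic and Langerhans cell markers had a median of 0.0028 over 13 (0.727), and were lower without control 2 (-0.72, 0.039). Cd207, the Langerhans cell lectin langerin, was at 262.4 ± 183.0 and 373.5 ± 268.1 CPM. Mast cell markers had a median of 0.75 over 6 (0.727), between 0.56 and 3.58 with 1 library left out. The histamine-forming enzyme Hdc was at 161.1 ± 7.72 and 114.7 ± 45.7 CPM. Gamma delta T cell markers had a median of 0.89 over 5 (0.618), with Trdc, the delta chain constant region, at 12.2 ± 17.3 and 22.7 ± 13.4 CPM. B cell markers had a median of 0.94 over 5 (0.727), led by the immunoglobulin gene Igkc with 60, 14, 4738 and 12 fragments in control 1, control 2, knockout 1 and knockout 2. CD8 and cytotoxic markers had 2 tested members and no list test, with the protease Gzmb at 178.7 ± 5.97 and 84.8 ± 69.7 CPM, and of erythroid markers only the globin gene Hbb-bs was tested, with 0, 104, 51 and 0 fragments. Glycolysis genes had a median of 0.67 over 15 (0.377), oxidative phosphorylation genes -0.02 over 62 (0.148), heat shock genes 0.02 over 13 (0.597) and p53 response and apoptosis genes 0.38 over 19 (0.983). With 1 library left out, the glycolysis median lay between 0.32 and 0.85 and the oxidative phosphorylation median between -0.24 and 0.09.

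The median, the mean and the list test differed in sign for 6 lists, none past the threshold. They are the p53 response (median 0.38, test lower), naive and central memory (median -0.04, mean 0.48, test lower), JAK-STAT (median -0.04, mean 0.26, test higher), heat shock (median 0.02, mean -0.01, test lower), dendritic (median 0.0028, mean 0.05, test lower) and endothelial (median 0.25, mean -0.30, test lower) lists.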

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

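The covariate for Y-linked transcripts, the minimum of 1 fragment in every library and the sums without retained-intron exons were chosen after seeing the data, and the other alternatives were planned. The count of genes past the threshold was 0 with all 4 libraries and in 13 of 17 alternatives. It was 17 with DESeq2 and 27 without a low-count filter, where the genes tested were 24651, and between 0 and 4 with 1 library left out. At an adjusted p under 0.1, with all 4 libraries, DESeq2 called 18 genes and edgeR without the filter 41. The count without control 1 depended strongly on the threshold, with many genes only slightly above it. Without control 1, the median log2 fold change of all genes was 1.72, against 0.20 with all libraries. The only control was then control 2, which had 0 fragments in 4064 of the 12434 genes tested with all libraries. The count of lists past the threshold was 9, between 5 and 11 with 1 library left out, 0 with an estimated correlation and 0 with fry, which use other estimates of how genes move together. The Mettl3 log2 fold change was 0.28, stayed positive in 14 of 15 alternatives and lay between -0.34 and 1.45 with 1 library left out and at 1.59 without retained-intron exons. DESeq2 has no list test and was not run for the lists. A setting without 1 library leaves a genotype with a single library, which is assumed to vary like the other genotype's. No paired analysis was possible because the labels number no replicates.

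Of 974 recomputed gene values, 927 kept direction and side of the threshold, 14 passed it and 33 reversed. Those that passed included Map3k4, Lrat, Lce3d, Bbox1 and Sprr2k with DESeq2, Lrat, Bbox1, Sprr2k, Krt1, Lgals7, Igkc and Perp without a low-count filter, and Igkc without knockout 2. The cause of a reversal was not tested. Cd4 reversed with limma-voom (1.33) and the Y-linked covariate (1.10), as did Cd3e (1.29 and 1.42). S100a8 reversed without retained-intron exons (-0.13). Mmp2, at -0.01, reversed with upper-quartile factors (0.039), no low-count filter (0.029), limma-voom (0.44), the covariate (0.48) and no retained-intron exons (0.033). With 1 library left out, log2 fold changes ranged for Il17f from -4.63 to 2.23, Ifng from -9.68 to 1.17, Cish from -0.96 to 9.10, Cd4 from -5.31 to 10.77, Cd3e from -2.05 to 5.73, Rpl39 from -1.86 to 0.24, mt-Atp6 from -2.92 to 1.04, mt-Tn from -3.47 to 0.29, mt-Nd2 from -1.73 to 0.16, mt-Nd6 from -1.91 to 0.21, Trdc from -0.11 to 9.53, Igkc from -1.55 to 7.39, Cd207 from -0.50 to 1.56, Perp from -4.98 to 0.25, Mmp2 from -0.82 to 1.99, Plvap from -2.79 to 0.64 and Hbb-bs from -8.78 to 7.77.

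Of 522 recomputed list values, 430 kept direction and side, 15 passed the threshold, 40 lost it and 37 reversed in the direction of the list test, with these median log2 fold changes. Follicular helper genes reversed with the covariate (0.19) and fry (-0.47). Naive and central memory genes reversed without a low-count filter (0.11), at a mean of at least 5 CPM (0.0077) or for members at that mean (-0.035), and with fry (-0.035). The p53 list reversed with upper-quartile factors (0.44), no filter (0.60), a mean of at least 5 CPM (0.27), limma-voom (0.54), a fragment in every library (0.30), no retained-intron exons (0.49) and fry (0.38). Heat shock genes reversed with a fragment in every library (-0.0072) and fry (0.016), B cell markers with limma-voom (1.19), m6A readers and erasers without retained-intron exons (0.33), and dendritic (0.0028) and endothelial (0.25) markers with fry. With 1 library left out, medians ranged for JAK-STAT genes from -0.26 to 3.36, type 2 genes from -3.01 to 6.99, follicular helper genes from -0.75 to 8.37, naive and central memory genes from -1.11 to 1.45, tissue residency genes from -0.12 to 1.10, p53 genes from 0.015 to 1.49, ribosomal protein genes from -0.62 to 0.17, mitochondrially encoded genes from -1.62 to 0.38, heat shock genes from -0.054 to 0.21, gamma delta markers from -2.88 to 8.13, B cell markers from -1.55 to 5.33, dendritic markers from -1.62 to 1.56, fibroblast markers from -1.08 to 1.97 and endothelial markers from -1.73 to 0.64.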

Other observations

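All tests of explanations were chosen after the results were seen, as were the further genes named here. Apart from the lists, 6 genes were picked from among those with both knockouts above both controls, so their shared direction follows from the choice, and none passed the threshold with the low-count filter. Without the filter 4 of them did, Thbs1 (adjusted p = 0.0031), Fpr1 (0.0096), Acod1 (0.0096) and Chil3 (0.031). Thbs1, the matrix glycoprotein thrombospondin 1, was at 2455 CPM in control 1, 896 in control 2, 13790 in knockout 1 and 5234 in knockout 2 (log2 fold change 2.51, standard error 0.79, edgeR adjusted p = 0.9997). Chil3, a chitinase-like protein of macrophages, was at 1685, 510.5, 6575 and 4331 CPM in the same order, Arg2, an arginase, at 214.4, 152.8, 1196 and 581.5, and Ms4a4a at 360.0, 149.9, 1477 and 924.8. Acod1, which makes itaconate, was at 474.6, 19.5, 2562 and 1616 CPM, and Fpr1, a receptor for bacterial formyl peptides, had 563, 0, 3211 and 3701 fragments.

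Some values belong to single libraries. Igkc was at 1183 CPM in knockout 1 and at most 13.1 elsewhere, and the variable segments Igkv8-34, Igkv14-111 and Ighv5-17 had 1839, 1402 and 1205 fragments there and at most 1 in each other library. Xist, transcribed from the inactive X chromosome, had 1858 fragments in control 1, 8909 in control 2, 5442 in knockout 1 and 20 in knockout 2. The Y-linked genes Eif2s3y, Kdm5d and Uty had 44, 14 and 18 fragments in control 1 and 55, 19 and 41 in knockout 2, and 0 in control 2 and knockout 1, so control 1 held both kinds of transcript. Ddx3y had at most 3 fragments in any library. A gate on CD45 would remove keratinocytes and one on CD4 most macrophages and gamma delta T cells, and the gate used is not given in the sources used here. Retained-intron exons held 7.63% of fragments in control 1 (exact 95% interval 7.60 to 7.65), 7.23% in control 2 (7.20 to 7.25), 9.33% in knockout 1 (9.31 to 9.36) and 8.89% in knockout 2 (8.86 to 8.91), and a difference between 2 and 2 libraries cannot go below an exact permutation p of 0.3333.

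Control 2 lacked fragments of many genes that the other libraries held. The tables argue against lower depth, since the other libraries thinned to its total still had fragments of at least 16033 genes against 11424. Dilution by keratinocyte RNA would thin other genes in proportion, but of 3903 genes with at least 100 fragments in each other library, 347 had 0 in control 2, while Lyz2 kept 41.3% of its lowest level elsewhere. The same count was 0 of 2899 for control 1, 0 of 3047 for knockout 1 and 3 of 2970 for knockout 2. A small amount of starting RNA may be the source, a candidate explanation that was not tested because the labels give no cell numbers, and no biological explanation was tested, since the other control has the same genotype.

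The interferon list, which shares 0 genes with the macrophage list, was higher in the knockouts with a preset correlation, but not past the threshold with an estimated correlation (adjusted p = 0.940) or fry (0.906). Genes missing from control 2 were not the whole source of the preset-correlation call, which stayed without that library at a median log2 fold change of 1.46. More macrophage RNA in the knockouts may account for it: against control 1, the median log2 ratio of interferon genes exceeded that of macrophage markers by 0.69 in knockout 1 (bootstrap standard error 0.34) and by 0.39 in knockout 2 (0.38). The bootstrap resampled each list's genes as if independent, so its error covers no spread between libraries. The estimated correlation between genes was 0.405 in the interferon list and 0.472 in the macrophage list. Summed interferon fragments per 100 macrophage fragments were 3.461 in control 1, 2.702 in control 2, 6.575 in knockout 1 and 3.398 in knockout 2. Knockout 2 thus lay below control 1 by this measure. The share of macrophage RNA cannot be told apart from a higher level per cell. A genotype difference stays open for both lists. The daily amount of imiquimod, 15 or 62.5 mg, is not given per mouse. A difference in that amount cannot be told apart from one in genotype.

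The type 3 cytokines Il17a, Il17f and Il22 had 2071 fragments in control 1, 314 in control 2, 381 in knockout 1 and 19 in knockout 2, fewer on average in the knockouts but with knockout 1 above control 2. A smaller T cell share alone predicts no genotype difference in these fragments per 100 T cell identity fragments, and overlap between genotypes was taken as its sign. That holds only if the identity fragments come from T cells, and the list includes genes not limited to them, such as Ptprc, which encodes CD45. The ratios were 32.9 in control 1 (exact 95% interval 31.3 to 34.6), 19.6 in control 2 (17.3 to 22.1), 13.5 in knockout 1 (12.1 to 15.0) and 1.22 in knockout 2 (0.733 to 1.91). They did not overlap, so that prediction was not met. RNA of other cells in the denominator could lower the ratio too, so this does not count against a smaller T cell share. Chance alone puts both knockouts below both controls 16.7% of the time. The gap of 6.13 between the lowest control and the highest knockout was smaller than the range within controls (13.3) and within knockouts (12.3). The denominator also matters. Trac, a list member named for its low p, had 906 fragments in control 1, 277 in control 2, 140 in knockout 1 and 108 in knockout 2. Per Trac fragment, the cytokines in knockout 1 lay above both controls. A smaller T cell share and a difference between genotypes within T cells therefore cannot be told apart with 2 libraries each. Gamma delta T cells, most of which a gate on CD4 would remove, could also supply these cytokines, which was not tested: their markers had 350 fragments in control 1, 0 in control 2, 287 in knockout 1 and 165 in knockout 2, and control 2 held the cytokines without them but lacked many other genes too.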
